A study of Rattus norvegicus with 8 samples.

How the data were processed

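Hippocampal total RNA from male Sprague Dawley rats was labelled with Cy3 by the authors and hybridised to Agilent rat gene expression arrays, 1 array per sample. The 8 arrays lay on 1 slide and were scanned in 1 session, with normoxia and day 1 in slide row 1 and day 3 and day 7 in row 2. Normoxia and day 3 lay in columns 1 and 2, and day 1 and day 7 in columns 3 and 4. Groups were taken from the labels: normoxia, day 1, day 3 and day 7, with 2 arrays each. The group titled day 7 carries 5 days in its exposure field. The arrays numbered 1 and 2 in different groups were not treated as pairs, because deviations from the group means did not correlate between groups (-0.15 to 0.05).

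The deposited scanner output holds, per the file headers, processed signal intensity for each spot from Agilent Feature Extraction 11.5.1.1, background-subtracted and detrended within the array and not scaled between arrays. Per the file headers it also holds the mean signal intensity of each spot and the median intensity of its local background. The deposited values of the series is in log2 units; the authors do not state its scaling, and its values were found to be log2 processed signal minus the array's 75th percentile, with 96.9% to 97.6% of values within 0.05 after 1 constant per array. The main analysis used the processed signal, and the deposited values served as an alternative.

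Control spots and spots marked as outliers by the scanner software were left out, the log2 signals of a probe's spots were averaged, and each array's 75th percentile over 30367 probes was subtracted. Probes were kept when well above background on both arrays of at least 1 group, which left 24678 of 30346 complete probes. A gene was represented by its kept probe with the highest mean over all 8 arrays, which gave 21296 genes, of which 14460 carry a gene symbol. Symbols are those of the array annotation on rat genome build rn4, with the current symbol added where the reference gave another. Probe coordinates are those of that annotation. No depth applies to arrays, and their number limits the precision.

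Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default prior) in 1 model with a mean per group, with two-sided tests and Benjamini-Hochberg adjustment over all 21296 genes in each comparison. A gene was called at an adjusted p under 0.05. The model had 4 residual degrees of freedom, a prior of 1.22 degrees of freedom and a median residual SD of 0.074 log2. There were 5 comparisons, 3 with normoxia and 2 between consecutive groups, and a moderated F-test for any difference among the 4 groups. Tables were read and written with the data.table package, version 1.17.8, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

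Genes were named by a rule fixed before the data were examined, as were the lists and most alternatives. For each comparison with normoxia these were the 10 largest rises and the 10 largest falls among called genes with a symbol whose arrays lay on a single side of both reference arrays. Between consecutive groups the 5 largest of each direction were taken. Not every gene that met the rule is reported. Up to 4 members with the smallest p were named from each described list, and Vegfa, Slc2a1, Pdk1, Adm, Hif3a, Fkbp5, Sgk1, Ttr, Gfap, Bdnf and Fos were given whatever their result. Other genes named in the account of overlaps and in the other observations were chosen after their values were seen. Where a gene was not well above background on either array of the lower group, that group was set to the higher of its signal and the lowest signal called well above background on the array, and the fold is given as at least that size.

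Before the data were examined, 37 gene lists of pathways and cell types were fixed, including markers of neighbouring tissues. They were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Another 4 lists, of midbrain dopamine neuron, hypothalamic neuropeptide, neutrophil and platelet genes, were added after the data were seen and adjusted separately. The median change of each list was set beside 10000 random lists matched on mean level. The overlap of the comparisons was set beside 100 simulated data sets with no effect, which share the normoxia arrays as the data do.

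Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' values, no filter, a filter on all 8 arrays, the mean of a gene's probes, an intensity trend in the prior, only the 2 groups compared, the replicate number as a block, thresholds with a fold of 2, and leaving out each array. Removing each array's trend with probe GC, leaving out the day 1 arrays and leaving out neighbouring-tissue genes were added after the data were seen. The procedure was tested on simulated data of 21296 genes, with changes in 50 genes of each size and noise drawn from the residual SD of the arrays. A log2 change of 2 was called in 42, 42 and 38 of them on days 1, 3 and 7. A change of 1 was called in 37, 29 and 38, and a change of 0.5 in 20, 24 and 21. A change of 0.25 was called in 3, 1 and 1, with 13, 8 and 7 false calls among unchanged genes. The cutoff set by the adjustment depends on the share of changed genes. That share was far smaller in the simulation than the 35.5% to 61.3% of genes called against normoxia. These rates therefore may not apply to the data. Other splits of the arrays were not counted, since groups of 2 are too small for it.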

Results

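Gene expression was measured in the hippocampus of male Sprague Dawley rats kept in normoxia or in a decompression chamber at low air pressure (hypobaric hypoxia, 25000 ft, 8% oxygen). RNA was hybridised to 8 single-colour Agilent arrays, 2 for each of 4 groups: normoxia and the groups titled day 1, day 3 and day 7. The labels of the last group disagree, since its titles give day 7 and its exposure field gives 5 days; it is called day 7 here, and which duration applies stays open. No label says that the 2 arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical. Arrays of a group differed by a median of 0.057 to 0.078 log2 per gene above background. For probes on 10 spots the median difference was 0.020, 0.025 and 0.027 on days 1, 3 and 7. Variation between spots alone would give 0.017, 0.019 and 0.023. In normoxia it was 0.041 against 0.014. The exposed arrays thus differed little more than spots did, as repeats of 1 RNA also would, so the calls may not carry over to other animals. Values are log2 signals relative to each array's 75th percentile, changes are log2 differences of group means ± SE with n = 2 arrays per group, and adjusted p-values come from limma over 21296 genes.

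The signal of sample probes fell over the exposure. The share of spots well above background was 85.6% and 84.5% in normoxia, 80.6% and 82.1% on day 1, 75.7% on each day 3 array, and 77.0% and 72.6% on day 7. The 75th percentile of the processed signal was 4056 and 3494 in normoxia, 3315 and 3368 on day 1, 2704 and 2457 on day 3, and 2329 and 2298 on day 7. Spike-in RNA did not follow this course: the log2 signal of control probe E1A_r60_a97 was 13.42 and 13.18 in normoxia, 12.72 on each day 1 array, 12.97 and 12.78 on day 3, and 13.11 and 13.04 on day 7. Genes of high signal rose relative to genes of low signal: the Spearman correlation across genes between change and mean level was 0.22 on day 1, 0.38 on day 3 and 0.43 on day 7, where genes are not independent replicates. In the brightest decile of genes the median day 7 change was 0.36, and in the dimmest decile it was -0.65. Gene lists are therefore given, where it matters, beside random lists matched on mean level. These random lists were drawn as independent genes and vary less than lists of genes that move together. An extreme percentile alone therefore does not show a change. Of the 21296 genes, 21131 were well above background on both normoxia arrays, against 20035, 18229 and 17901 on days 1, 3 and 7. Genes near background in exposed groups thus passed the filter mostly through normoxia. This may add to the falls of the dimmest decile.

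**Figure D1:**
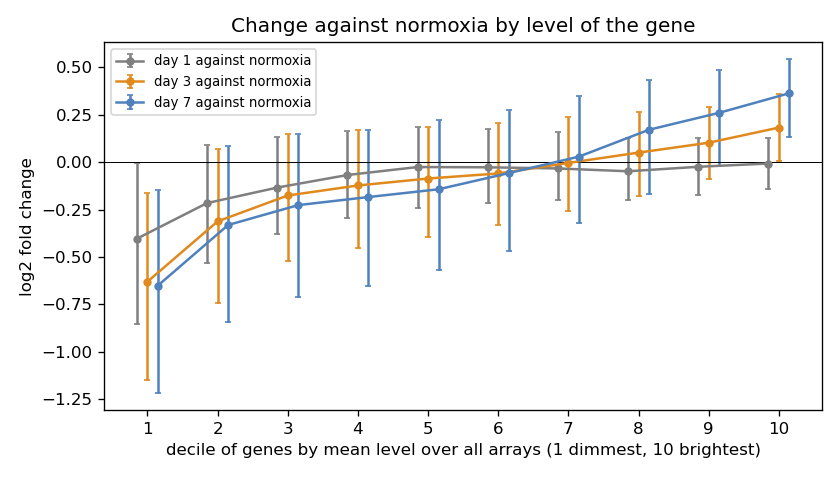
Log2 fold change against normoxia (vertical axis) by decile of genes ranked on mean level over all 8 arrays (horizontal axis, 10 is the brightest), with medians as points and quartiles as bars, for days 1, 3 and 7. The brightest decile had a median of 0.36 on day 7 and the dimmest decile a median of -0.65.

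The first comparison asked what 1 day of hypobaric hypoxia changed in the hippocampus. Most genes of the hypoxia response rose, while genes of blood vessels went both ways. Angpt2, which encodes a vessel-destabilising growth factor, rose 37.2-fold (log2 change 5.22 ± 0.05, adjusted p = 3.3e-06), with its probe on rn4 chromosome 16 from 75939239 to 75939298. Vegfa, the main vascular endothelial growth factor, rose 6.43-fold (2.68 ± 0.07, adjusted p = 3.65e-05; chromosome 9, 10535933 to 10535992), and its other 3 probes gave 2.24 to 3.13. Of 37 tested HIF target genes, 26 rose and 1 fell (27 and 1 adjusted over the list alone; camera adjusted p = 2.61e-13, and adjusted p = 0.022 with an estimated correlation). Slc16a3, a lactate transporter, rose by 2.49 ± 0.04, Adm, a vasodilator peptide, by 1.80 ± 0.04, Ankrd37 by 1.38 ± 0.03, and the glucose transporter Slc2a1 by 1.28 ± 0.04. Pdk1, a kinase that limits pyruvate entry into mitochondria, rose by 0.35 ± 0.04. Hif3a did not pass the test (-0.17 ± 0.41).

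Of 28 genes of angiogenesis and vascular remodelling, 14 rose and 8 fell on day 1 (15 and 8 adjusted over the list alone; adjusted p = 0.00130, and adjusted p = 0.187 with an estimated correlation). The vessel basement membrane gene Col4a1 rose by 2.82 ± 0.06, against 1.56 on its other probe, and the VEGF receptor gene Kdr by 2.04 ± 0.04. Among 27 endothelial markers, 12 rose, with Pecam1 at 2.47 ± 0.05 and Flt1 at 2.08 ± 0.05, and 6 fell, with Abcg2, a transporter of the blood-brain barrier, at -2.08 ± 0.04 (12 and 8 adjusted over the list alone). As a list they did not pass (adjusted p = 0.0548). Glycolysis genes rose in 11 of 19 cases and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 7.35e-06, and 0.033 as the adjusted p with an estimated correlation). Examples were Aldoa at 0.72 ± 0.03 and Gpi at 0.49 ± 0.04. Oxidative phosphorylation genes fell in 36 of 60 cases and rose in 1 (39 and 1 adjusted over the list alone; adjusted p = 7.84e-08, and 0.029 as the adjusted p with an estimated correlation). Examples were Ndufa10 at -0.97 ± 0.04 and Ndufb5 at -0.51 ± 0.04, both of complex I.

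Cholesterol synthesis genes fell on day 1 in 22 of 27 cases and rose in 1 (24 and 1 adjusted over the list alone; adjusted p = 1.4e-08, and 0.024 as the adjusted p with an estimated correlation). The sterol demethylase gene Cyp51 fell by 0.84 ± 0.04, Mvd by 1.17 ± 0.06 and Sqle by 0.76 ± 0.04. Red blood cell genes rose in 7 of 9 cases with none falling (7 adjusted over the list alone; adjusted p = 7.35e-06, and 0.046 as the adjusted p with an estimated correlation). The band 3 anion exchanger gene Slc4a1 rose by 3.53 ± 0.08, the alpha-haemoglobin chaperone gene Ahsp by 3.33 ± 0.05, the erythroid haem synthesis gene Alas2 by 1.73 ± 0.05 and the beta-globin gene Hbb-b1 by 0.97 ± 0.05. Genes of the glucocorticoid response rose in 13 of 22 cases and fell in 2 (13 and 2 adjusted over the list alone; adjusted p = 6.45e-06, and 0.031 as the adjusted p with an estimated correlation). Examples were the transglutaminase gene Tgm2 at 2.03 ± 0.05, the metallothionein gene Mt2A at 1.62 ± 0.04, Fkbp5 at 0.30 ± 0.05 and Sgk1 at 0.29 ± 0.05. Fkbp5 and Sgk1 each lost their call without either day 1 array.

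Interferon response genes rose in 13 of 27 cases and fell in 1 on day 1 (15 and 1 adjusted over the list alone; adjusted p = 2.43e-04, and adjusted p = 0.063 with an estimated correlation). Examples were Ifit3 at 2.05 ± 0.08, Rsad2 at 1.88 ± 0.06, Gbp2 at 1.61 ± 0.05 and Mx1 at -0.72 ± 0.04. Immediate early genes, which neurons switch on with activity, rose in 15 of 28 cases and fell in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.00887, and adjusted p = 0.169 with an estimated correlation). The phosphatase gene Dusp1 rose by 1.00 ± 0.07, Egr2 by 0.61 ± 0.03, Egr1 by 0.50 ± 0.03 and Fos by 0.48 ± 0.06, while the neurotrophin gene Bdnf fell by 0.75 ± 0.04. Apoptosis and p53 targets rose in 8 of 25 cases and fell in 4 (8 and 4 adjusted over the list alone; adjusted p = 0.00887, and adjusted p = 0.095 with an estimated correlation). Examples were Ccng1 at 1.70 ± 0.07 and Bbc3 at 0.61 ± 0.04. Neurogenesis genes fell in 11 of 15 cases and rose in 2, including Calb2 at -0.75 ± 0.05 and Dcx, a marker of newborn neurons, at -0.51 ± 0.05 (11 and 3 adjusted over the list alone; adjusted p = 0.0390, and adjusted p = 0.262 with an estimated correlation). Oligodendrocyte precursor markers fell in 6 of 10 cases, with none rising and Neu4 at -1.03 ± 0.04 (6 and 1 adjusted over the list alone; adjusted p = 0.0446, and adjusted p = 0.184 with an estimated correlation). MHC class II genes, which present antigens, fell in 4 of 7 cases, with Cd74 at -1.62 ± 0.08 and RT1-Da at -1.28 ± 0.10 (4 adjusted over the list alone; adjusted p = 0.0336, and adjusted p = 0.169 with an estimated correlation). The astrocyte filament gene Gfap fell by 0.34 ± 0.05.

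Of the 37 fixed lists, choroid plexus and striatal markers had the largest median changes on day 1. All 20 choroid plexus markers fell, with a median change of -2.98 (20 adjusted over the list alone; adjusted p = 1.24e-15, and 0.022 as the adjusted p with an estimated correlation). Ttr, the transthyretin gene of the choroid plexus, fell 91.7-fold (-6.52 ± 0.07; chromosome 18, 12413621 to 12413680), Sostdc1 fell 85.9-fold (-6.43 ± 0.05) and Kcnj13 fell 28.7-fold (-4.85 ± 0.10). Tmem27 (now Cltrn) was not well above background on day 1 and was at least 96.7-fold lower, and Glycam1 at least 38.2-fold, Mfrp at least 25.6-fold, Cldn2 at least 23.9-fold, Lect1 (now Cnmd) at least 23.9-fold and Kl at least 18.7-fold lower. Conversely, all 15 tested striatal markers rose, with a median change of 2.37 (15 adjusted over the list alone; adjusted p = 1.17e-14, and 0.022 as the adjusted p with an estimated correlation). The adenosine receptor gene Adora2a rose 24.4-fold (4.61 ± 0.04), the dopamine receptor gene Drd2 by 3.29 ± 0.04 and Rgs9 by 3.30 ± 0.06. Lhx8 rose by 4.45 ± 0.10, Gpr6 was at least 11.1-fold higher (18.7-fold with day 1 replicate 1 alone and 6.63-fold with replicate 2), and Penk, a dentate list member that striatum also expresses, rose by 3.17 ± 0.03. Markers of leptomeninges and fibroblasts fell in 16 of 19 cases, with Igf2 at -1.58 ± 0.04 and Col1a2 at -1.47 ± 0.04, while Fn1 alone rose, by 1.83 ± 0.05 and by 0.37 on its other probe (17 and 1 adjusted over the list alone; adjusted p = 5.13e-08, and 0.024 as the adjusted p with an estimated correlation). Ependyma and cilia markers fell in 10 of 14 cases and rose in 1, with Rsph1 at -0.78 ± 0.06 (10 and 1 adjusted over the list alone; adjusted p = 0.00228, and adjusted p = 0.094 with an estimated correlation). Neocortex markers rose in 7 of 14 cases and fell in 3, with Lamp5 at 1.21 ± 0.07 (8 and 4 adjusted over the list alone; adjusted p = 0.0390, and adjusted p = 0.187 with an estimated correlation). Thalamus markers fell in 10 of 17 cases and rose in 3, and did not pass as a list (adjusted p = 0.0732).

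**Figure D2:**
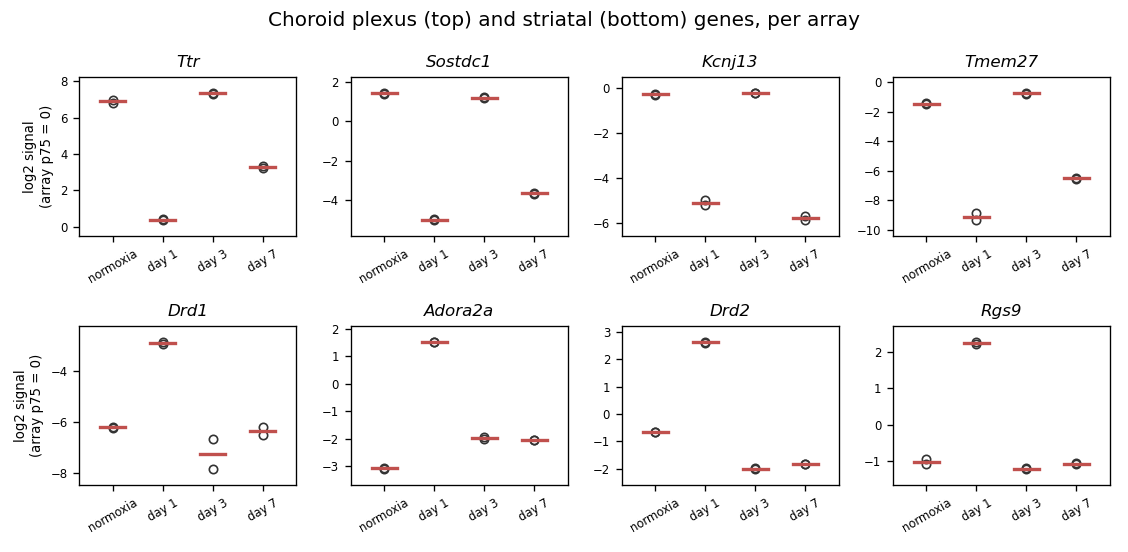
Log2 signal relative to the 75th percentile of the array (vertical axis, a separate scale for each gene) for choroid plexus genes (top) and striatal genes (bottom) in normoxia and on days 1, 3 and 7 (horizontal axis), with each array as a circle and the mean of 2 arrays as a line. Ttr changed by -6.52, 0.44 and -3.63 on days 1, 3 and 7, and Adora2a rose by 4.61 on day 1.

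The other genes of largest change on day 1 were Abca4 (3.96 ± 0.16), Mall (3.82 ± 0.04), Dmkn (3.71 ± 0.14), Serpinb11 (at least 7.52-fold higher) and Lypd8 (3.62 ± 0.10, against 0.90 on its other probe). Slc6a3, the dopamine transporter gene of midbrain neurons, was at least 73.3-fold lower, and its other probe fell by 2.58. In all, 7559 of 21296 genes were called on day 1, 3258 higher and 4301 lower, and 313 and 448 of these changed at least 2-fold. With each array's trend with probe GC removed, an alternative added after seeing the data, 57.7% of calls were higher, against 43.1%. Of 18 list calls on day 1, those of choroid plexus, striatum, HIF targets, cholesterol synthesis, leptomeninges, oxidative phosphorylation, glucocorticoid response, glycolysis and red blood cells held with an estimated correlation, and none of the 12 on day 3 or the 11 on day 7 did. Leaving out 1 array moved this count to 4984 without normoxia replicate 2, 4350 without day 1 replicate 1 and 4382 without day 1 replicate 2. With the genes of the neighbouring-tissue lists left out, an alternative added after seeing the data, 7480 calls stood. Only list members were dropped and the fit was not repeated. This count therefore cannot show whether other calls come from neighbouring tissue.

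The second comparison asked what had changed after 3 days. Most HIF target genes were higher than in normoxia, and vessel genes again went both ways. Vegfa was up 6.23-fold (2.64 ± 0.07, adjusted p = 5.21e-05, and 2.01 to 2.33 on its other 3 probes), Angpt2 by 3.23 ± 0.05, Slc16a3 by 2.05 ± 0.04, Adm by 1.68 ± 0.04, Ankrd37 by 1.39 ± 0.03 and Slc2a1 by 0.94 ± 0.04, whereas Pdk1 was lower than in normoxia (-0.28 ± 0.04, and -0.13 and not called under median centring). Of 37 HIF target genes, 21 rose and 5 fell (23 and 6 adjusted over the list alone; adjusted p = 1.23e-04, and adjusted p = 0.084 with an estimated correlation). Kdr rose by 2.07 ± 0.04, Flt1 by 1.89 ± 0.05 and Pecam1 by 1.88 ± 0.05, among 12 endothelial markers that rose and 6 that fell of 27 (12 and 7 adjusted over the list alone; adjusted p = 0.0918). Angiogenesis genes rose in 14 of 28 cases and fell in 8 (14 and 8 adjusted over the list alone), and did not pass as a list (adjusted p = 0.0732). Vegfb, another VEGF family gene, was not well above background on either day 3 array and was at least 29.9-fold lower there (adjusted p = 1.16e-05; chromosome 1, 209657830 to 209657889). Its value rests on 1 probe.

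Red blood cell genes rose in 8 of 9 cases on day 3, with a median of 1.65 (8 adjusted over the list alone; adjusted p = 1.45e-05, and adjusted p = 0.084 with an estimated correlation). Slc4a1 was up 19.1-fold (4.25 ± 0.08; chromosome 10, 91455352 to 91455411), Ahsp 16.2-fold (4.02 ± 0.05, and 4.14 on its other probe), Alas2 by 3.25 ± 0.05 and Hbb-b1 by 1.65 ± 0.05. The erythroid genes Hemgn (3.94 ± 0.09) and Rhag (at least 7.89-fold higher) rose as well. Alox15, a 15-lipoxygenase gene, rose 34.6-fold (5.11 ± 0.10), and Cd52, a surface antigen of leukocytes, rose 20.7-fold (4.37 ± 0.05). The potassium channel subunit gene Kcne3 was at least 26.1-fold higher, Defb17 at least 9.21-fold and the olfactory receptor gene Olr271 (now Or5p78) at least 6.70-fold higher (3.90-fold with day 3 replicate 1 alone and 11.52-fold with replicate 2). Vom2r30 was at least 25.7-fold higher on 1 probe (83.1-fold with day 3 replicate 1 alone and 7.94-fold with replicate 2) and at -0.73 on its other probe.

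**Figure D3:**
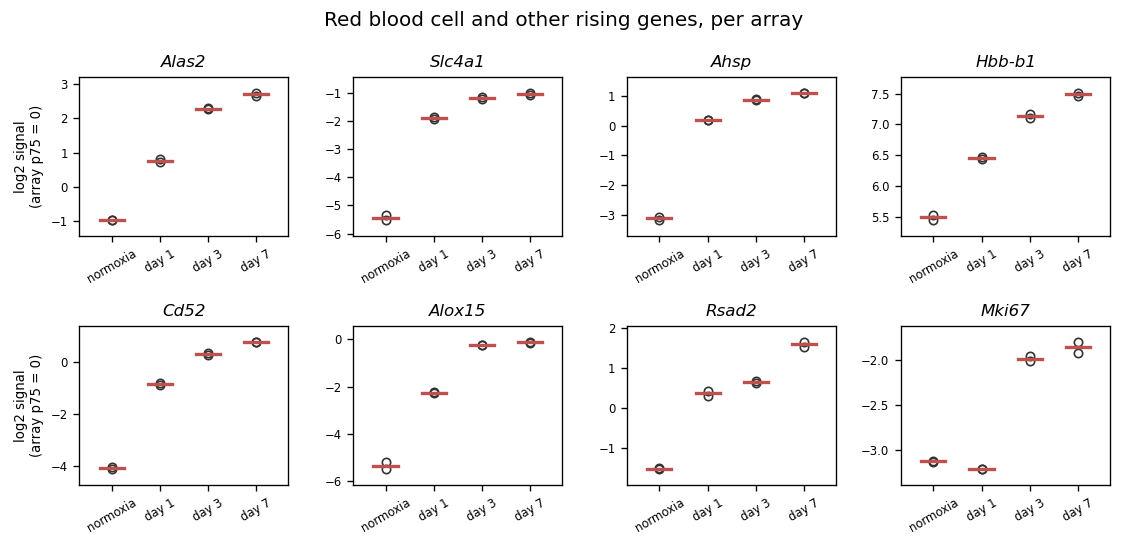
Log2 signal relative to the 75th percentile of the array (vertical axis, a separate scale for each gene) for red blood cell genes and 4 other rising genes in normoxia and on days 1, 3 and 7 (horizontal axis), with each array as a circle and the mean of 2 arrays as a line. Alas2 rose by 1.73, 3.25 and 3.67 and Ahsp by 3.33, 4.02 and 4.25 on days 1, 3 and 7.

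Cholesterol synthesis genes stayed low on day 3, falling in 20 of 27 cases with none rising (21 adjusted over the list alone; adjusted p = 2.49e-06, and adjusted p = 0.084 with an estimated correlation). Nsdhl fell by 1.03 ± 0.04, Cyp51 by 0.90 ± 0.04 and Fdps by 0.88 ± 0.04. Presynaptic and pan-neuronal genes fell in 16 of 24 cases and rose in 2 (17 and 2 adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.152 with an estimated correlation). Examples were the vesicle gene Rab3a at -1.18 ± 0.04 and the glutamate transporter gene Slc17a7 at -0.59 ± 0.05. Microglia markers fell in 14 of 23 cases and rose in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.0123, and adjusted p = 0.313 with an estimated correlation). Examples were Tmem119 at -0.92 ± 0.03 and Csf1r at -0.89 ± 0.04. MHC class II genes fell in 5 of 7 cases, with Cd74 at -1.15 ± 0.08 (5 adjusted over the list alone; adjusted p = 0.0173, and adjusted p = 0.201 with an estimated correlation). Interferon genes rose in 14 of 27 cases and fell in 3 (14 and 3 adjusted over the list alone; adjusted p = 0.0313, and adjusted p = 0.241 with an estimated correlation). Examples were Rsad2 at 2.17 ± 0.06, Gbp2 at 0.89 ± 0.05 and Mx1 at -0.93 ± 0.04. Myelin and oligodendrocyte markers fell in 13 of 25 cases and rose in 5, including Myrf at -1.15 ± 0.06 and Cnp at -0.93 ± 0.06, and did not pass as a list (adjusted p = 0.0852). Cell cycle genes rose in 16 of 28 cases and fell in 7, with Mki67 at 1.14 ± 0.05 and Cdk1 at 0.80 ± 0.05, and did not pass as a list (adjusted p = 0.0852). Mt2A (1.71 ± 0.04) and Tgm2 (1.45 ± 0.05) were high and Dusp1 low (-1.78 ± 0.07), and Gfap was at -0.87 ± 0.05 on its main probe and at -0.12 on its other probe.

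Ribosomal protein genes rose in 49 of 72 cases and fell in 1 on day 3 (55 and 1 adjusted over the list alone; adjusted p = 8.93e-11, and adjusted p = 0.241 with an estimated correlation). Examples were Rps15a at 0.58 ± 0.05 and Rpl21 at 0.56 ± 0.05. Their median of 0.31 lay at percentile 87.1 of random lists matched on level, whose median was 0.27, and with quantile normalization the list did not pass (median 0.031, adjusted p = 0.342). Oxidative phosphorylation genes went both ways on day 3, with 19 rising and 15 falling of 60 (adjusted p = 0.485), such as Ndufb3 at 0.56 ± 0.05 and Atp5b (now Atp5f1b) at -0.81 ± 0.04. With quantile normalization the list fell (median -0.13, adjusted p = 1.13e-04).

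Choroid plexus markers did not differ as a list from normoxia on day 3 (median -0.078, 4 rose and 6 fell of 20, adjusted p = 0.938), with Ttr at 0.44 ± 0.07 (0.064 and not called with quantile normalization). Striatal markers rose in 2 and fell in 8 of 15 cases (adjusted p = 0.194), with Drd2 at -1.35 ± 0.04. Leptomeningeal and fibroblast markers fell in 17 of 19 cases and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.084 with an estimated correlation). Examples were Col1a2 at -1.30 ± 0.04 and Dcn at -1.16 ± 0.03, while Fn1 rose by 1.99 ± 0.05, and by 0.20 on its other probe. Thalamus markers fell in 15 of 17 cases and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 7.56e-05, and adjusted p = 0.084 with an estimated correlation). Examples were Prkcd at -1.36 ± 0.03 and Tcf7l2 at -1.14 ± 0.05, against -0.14 on its other probe. Ependyma and cilia markers rose in 10 of 14 cases with none falling (10 adjusted over the list alone; adjusted p = 4.05e-04, and adjusted p = 0.104 with an estimated correlation). An example was Foxj1 at 0.87 ± 0.04. Neocortex markers fell in 7 of 14 cases, with Etv1 at -0.61 ± 0.07 (7 adjusted over the list alone; adjusted p = 0.0313, and adjusted p = 0.241 with an estimated correlation).

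Slc6a3 was at least 44.3-fold lower on day 3 and its other probe fell by 3.48. Foxa2, a transcription factor of midbrain dopamine neurons, was at least 5.53-fold lower, and Pmch, which encodes a hypothalamic neuropeptide, fell by 3.30 ± 0.04. Ovol1, above background on 1 of 2 day 3 arrays, fell by 3.39 ± 0.15, Msln was at least 8.32-fold lower, Defb1 at least 6.52-fold, Vom2r58 at least 5.66-fold, Cphx at least 4.41-fold and Cryba4 at least 4.39-fold lower. The normoxia arrays disagreed for 2 of these: replicate 1 alone gave 2.04-fold for Vom2r58 and 12.1-fold for Cphx, and replicate 2 alone 15.7-fold and 1.60-fold. With normexp background correction neither was called (-0.80 and -0.62). In all, 10719 genes were called on day 3, 5146 higher and 5573 lower, and 324 and 1185 of these changed at least 2-fold. Under median centring the median change of all genes was 0.10, against -0.05 in the main scaling, and 66.7% of calls were higher, against 48.0%. Normexp background correction gave 0.13 and 67.9%. With no filter 53.3% of calls were higher, and with the filter on all 8 arrays 52.6%. The day 3 and normoxia arrays lay in different rows of the slide, so row and group cannot be told apart in this comparison. The same holds for day 7 against normoxia and for day 3 against day 1. Normoxia and day 3 lay in slide columns 1 and 2, and days 1 and 7 in columns 3 and 4. Column and group therefore cannot be told apart in any comparison except day 3 against normoxia.

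The third comparison took the group titled day 7. The hypoxia genes Vegfa (5.67-fold higher, 2.50 ± 0.07, adjusted p = 3.06e-05, and 1.38 to 2.41 on its other 3 probes), Adm (1.44 ± 0.04), Slc16a3 (1.36 ± 0.04) and Slc2a1 (1.35 ± 0.04) were up, and Pdk1 was down (-0.33 ± 0.04, but -0.031 and not called under median centring). HIF target genes rose in 21 of 37 cases and fell in 9 and did not pass as a list (23 and 10 adjusted over the list alone; adjusted p = 0.0505). Angiogenesis genes went both ways, 10 higher and 13 lower of 28 (adjusted p = 0.947). The basement membrane gene Col4a1 was up by 2.25 ± 0.06 and the tip cell signal gene Dll4 by 2.05 ± 0.05, but their other probes gave -0.08 and -0.14. Pecam1 (1.54 ± 0.05), Flt1 (1.47 ± 0.05) and Kdr (1.42 ± 0.04) rose among 13 endothelial markers that rose and 7 that fell of 27 (adjusted p = 0.330).

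Red blood cell genes rose in 8 of 9 cases on day 7 with a median of 1.98 (8 adjusted over the list alone; adjusted p = 6.99e-05, and adjusted p = 0.175 with an estimated correlation). Hemgn was up 23.0-fold (4.52 ± 0.09), Slc4a1 21.1-fold (4.40 ± 0.08), Ahsp 19.0-fold (4.25 ± 0.05), Alas2 12.7-fold (3.67 ± 0.05) and Rhag at least 10.7-fold. Alox15 was up 37.8-fold (5.24 ± 0.10; chromosome 10, 57186202 to 57186261) and Cd52 28.7-fold (4.84 ± 0.05). Kcne3 was at least 11.1-fold higher and the olfactory receptor gene Olr1384 (now Or2v2) at least 5.61-fold higher (3.60-fold with day 7 replicate 1 alone and 8.76-fold with replicate 2). Interferon genes rose in 19 of 27 cases and fell in 3 (19 and 3 adjusted over the list alone; adjusted p = 9.63e-04, and adjusted p = 0.180 with an estimated correlation). Examples were the antiviral gene Rsad2 at 3.12 ± 0.06, Irf7 at 1.18 ± 0.06 and Isg15 at 1.08 ± 0.05. Cell cycle genes rose in 16 of 28 cases and fell in 5 (16 and 5 adjusted over the list alone; adjusted p = 0.0321, and adjusted p = 0.300 with an estimated correlation). Examples were Birc5 at 1.64 ± 0.06 and Mki67 at 1.27 ± 0.05. The list lost its call without normoxia replicate 2, where its median was 0.39. Glucocorticoid response genes rose in 11 of 22 cases and fell in 3 (adjusted p = 0.114), with Mt2A at 1.77 ± 0.04, Tsc22d3 at 1.01 ± 0.03 and Fkbp5 at 0.80 ± 0.05. The p53 target Ccng1 rose by 2.92 ± 0.07.

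Presynaptic and pan-neuronal genes fell in 15 of 24 cases and rose in 6 on day 7 (15 and 6 adjusted over the list alone; adjusted p = 0.0488, and adjusted p = 0.224 with an estimated correlation). Examples were Rab3a at -1.91 ± 0.04, the synapsin gene Syn1 at -1.13 ± 0.05 and the SNARE gene Snap25 at -0.83 ± 0.03. This call was lost without any single array of the exposed groups, with a median of -0.34 without day 7 replicate 1, -0.40 without day 7 replicate 2 and -0.37 without either array of day 1 or day 3. Of 32 glutamate receptor and postsynaptic genes, 11 rose and 13 fell (adjusted p = 0.649), including Dlgap1 at -1.97 ± 0.09, against -0.64 on its other probe, and the AMPA receptor gene Gria1 at -1.18 ± 0.03. Dusp1 (-2.11 ± 0.07), the activity-regulated gene Arc (-0.98 ± 0.03), Fos (-0.39 ± 0.06) and Bdnf (-0.22 ± 0.04) were low, though under median centring Fos was at -0.099 and Bdnf at 0.077 and neither was called, with 9 immediate early genes higher and 14 lower of 28 (adjusted p = 0.498). Gfap fell by 1.96 ± 0.05 on its main probe and was at 0.01 on its other probe, and the astrocyte gene Mlc1 fell by 1.31 ± 0.04. Cldn11 (-1.24 ± 0.04) and Cnp (-1.24 ± 0.06) fell among 13 lower and 8 higher of 25 myelin markers (adjusted p = 0.330), whose median of -0.21 lay at percentile 0.05 of level-matched lists (0.21). The microglial receptor gene Csf1r fell by 1.099 ± 0.043, Cd74 by 1.67 ± 0.08 and the dentate granule cell gene Calb1 by 0.80 ± 0.03. MHC class II genes fell in 5 of 7 cases (6 adjusted over the list alone; adjusted p = 0.0204, and adjusted p = 0.224 with an estimated correlation), and their median lay at percentile 27.7 of level-matched lists.

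Ribosomal protein genes rose in 68 of 72 cases on day 7 (68 adjusted over the list alone; adjusted p = 6.08e-13, and adjusted p = 0.224 with an estimated correlation). Examples were Rpl11 at 0.77 ± 0.05 and Rpl21 at 0.75 ± 0.05. Their median was 0.50 against 0.41 in lists matched on level, and with quantile normalization the list did not pass (median 0.066, adjusted p = 0.223). Oxidative phosphorylation genes rose in 41 of 60 cases and fell in 11 (41 and 11 adjusted over the list alone; adjusted p = 0.00393, and adjusted p = 0.194 with an estimated correlation). Examples were Ndufb3 at 0.85 ± 0.05 and Atp5b at -1.42 ± 0.04. Their median of 0.29 lay below that of level-matched lists, 0.38, at percentile 3.15, and with quantile normalization the list fell (median -0.094, adjusted p = 0.0201). With normexp background correction it did not pass (median 0.25, adjusted p = 0.718). Glycolysis genes rose in 10 of 19 cases and fell in 4 (adjusted p = 0.151), with Aldoa at -1.03 ± 0.03.

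Choroid plexus markers were low again on day 7, falling in 19 of 20 cases and rising in 1, with a median of -3.03 (19 and 1 adjusted over the list alone; adjusted p = 2.65e-08, and adjusted p = 0.114 with an estimated correlation). Kcnj13 fell 45.9-fold (-5.52 ± 0.10; chromosome 9, 86207003 to 86207062), Tmem27 and Sostdc1 each 33.8-fold (Kcnj13 and Tmem27 were above background on 1 of 2 day 7 arrays), Ttr 12.4-fold (-3.63 ± 0.07), Otx2 by 2.16 ± 0.04 and Steap1 by 2.36 ± 0.04. Glycam1 was at least 23.3-fold lower, Mfrp at least 15.9-fold, Lect1 and Cldn2 at least 14.0-fold, Tmem72 at least 12.9-fold and Kl at least 11.0-fold lower. Leptomeningeal and fibroblast markers fell in 17 of 19 cases and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 1.54e-06, and adjusted p = 0.114 with an estimated correlation). Examples were Col1a2 at -1.79 ± 0.04 and Igf2 at -1.77 ± 0.04, while Fn1 rose by 1.84 ± 0.05, and by 0.09 on its other probe. Thalamus markers fell in 11 of 17 cases and rose in 1, with Ramp3 at -1.07 ± 0.04 (12 and 1 adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.194 with an estimated correlation), at percentile 4.35 of level-matched lists and with a median of 0.017 under median centring. Neocortex markers fell in 8 of 14 cases and rose in 1, with Etv1 at -2.19 ± 0.07 (8 and 1 adjusted over the list alone; adjusted p = 0.0246, and adjusted p = 0.224 with an estimated correlation), at percentile 12.3 of level-matched lists and with a median of 0.065 under median centring. Striatal markers rose in 3 and fell in 9 of 15 cases (adjusted p = 0.151), with Drd2 at -1.19 ± 0.04.

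Slc6a3 was at least 43.0-fold lower on day 7, and its other probe fell by 2.81. In all, 13044 genes were called, 6717 higher and 6327 lower, and 407 and 2013 of these changed at least 2-fold. Under median centring the median change of all genes was 0.26 and 73.1% of calls were higher, and with normexp background correction these were 0.22 and 71.5%, against -0.03 and 51.5% in the main scaling. With no filter 56.3% of calls were higher, and with the filter on all 8 arrays 56.2%.

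**Figure D4:**
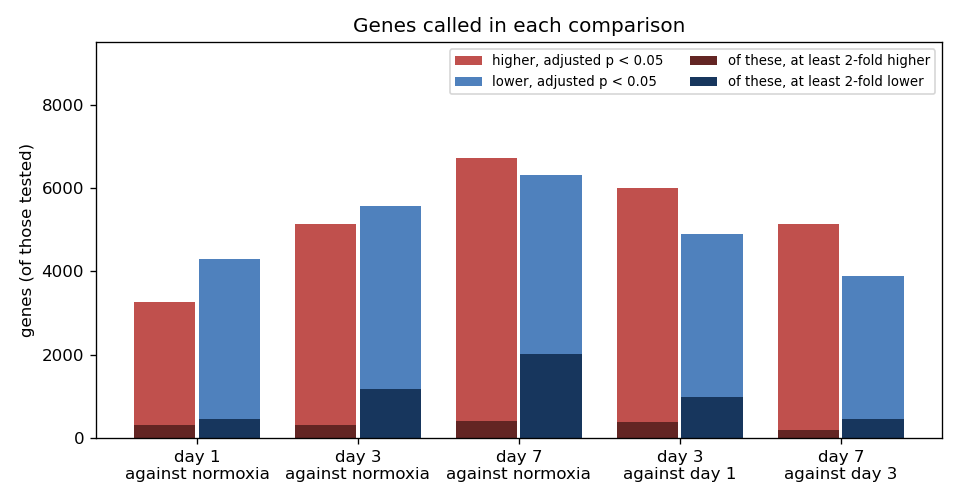
Number of genes past an adjusted p of 0.05 (vertical axis) in each of 5 comparisons (horizontal axis), higher in red and lower in blue, with genes changed at least 2-fold in the dark part of each bar. The total was 7559 on day 1, 10719 on day 3 and 13044 on day 7.

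Consecutive groups were compared to see how they differed. Choroid plexus genes were higher on day 3 than on day 1, and striatal genes were lower. Each group has its own samples, and different amounts of these tissues cannot be told apart from a response. The changes below are those of day 3 against day 1. Ttr rose 124-fold (6.96 ± 0.07, adjusted p = 4.17e-06), Sostdc1 rose 73.8-fold, Tmem27 was at least 158-fold and Glycam1 at least 91.5-fold higher. Lhx8 was at least 46.7-fold lower, Drd2 24.9-fold lower (-4.64 ± 0.04, and -3.40 on its other probe) and Drd1 at least 17.1-fold lower, and Vegfb was at least 37.5-fold lower. Vom2r30 was at least 20.6-fold higher on 1 probe (66.7-fold with day 3 replicate 1 alone and 6.37-fold with replicate 2) and at -0.06 on its other probe. Bdnf rose by 1.02 ± 0.04, and Fos fell by 0.85 ± 0.06 and Pdk1 by 0.63 ± 0.04. Vegfa did not pass (-0.05 ± 0.07, and -0.80 to 0.015 on its other 3 probes), although the mean of its probes did (-0.27). The count was 10913 genes, 6008 higher and 4905 lower, and 1380 at least 2-fold. Median centring gave 68.9% of calls as higher against 55.1% in the main scaling.

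On day 7 against day 3, Vegfb was at least 25.9-fold higher and choroid plexus genes were lower. Glycam1 was at least 55.9-fold lower, and Sostdc1 29.0-fold and Tmem72 at least 20.3-fold lower. Kcnj13 was 47.7-fold (-5.58 ± 0.10) and Tmem27 55.1-fold (-5.78 ± 0.15) lower, each above background on 1 of 2 day 7 arrays. Seli (now Selenoi), a phospholipid synthesis gene, rose 8.31-fold (3.06 ± 0.06), and Adam32 (at least 3.71-fold), Obp3 (at least 3.15-fold) and Trdn (at least 2.67-fold, against a log2 change of -1.16 on its other probe) were higher. Gfap fell by 1.09 ± 0.05 and by contrast was at 0.14 on its other probe, Fkbp5 rose by 0.58 ± 0.05 and Slc2a1 by 0.41 ± 0.04, and Vegfa did not pass (-0.13 ± 0.07, and -0.95 to 0.16 on its other 3 probes). The count was 9034 genes, 5146 higher and 3888 lower, and 650 at least 2-fold. With only these 2 groups in the fit it was 5358, and median centring gave 77.2% of calls as higher against 57.0% in the main scaling.

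Any difference among the 4 groups was found in 15348 genes, or 72.1% of those tested. Genes called in all 3 comparisons with normoxia in a single direction numbered 2804, of which 1330 were higher and 1474 lower, and 73 and 175 of these changed at least 2-fold on every day. Among them were Vegfa, Slc4a1, Ahsp, Rhag, Hemgn, Cd52, Alox15, Kcne3, Rsad2 and Col4a1, all higher, and Slc6a3, Foxa2 and Pmch, all lower. The other probe of Col4a1 did not rise on day 7, as given above. Slc6a3, Foxa2 and Pmch are genes of midbrain or hypothalamic neurons. More of such tissue in the shared normoxia samples cannot be told apart from a fall with exposure. Another 1451 genes were called on all 3 days in mixed directions. The comparisons share their normoxia arrays. Independent lists of the observed sizes would give 248 higher and 334 lower genes. In 100 simulated sets with no effect there were 0 such genes, but adjusted tests call almost no gene where nothing changes. The simulation therefore cannot show how many of the 2804 come from the shared arrays. Without normoxia replicate 2 the count was 1802, without day 1 replicate 1 it was 1668 and without day 1 replicate 2 it was 1697. Days 3 and 7 shared 4302 higher and 4147 lower genes with 446 in opposite directions, against 1623 and 1656 for independent lists. Days 1 and 7 shared 1564 higher and 1828 lower genes with 2342 in opposite directions (1028 and 1278 for independent lists), and days 1 and 3 shared 1625 and 2072 with 1389 opposite (787 and 1126). Simulated sets with no effect shared 0.02 genes or fewer on average, which has the same limit. Across genes, the changes on days 3 and 7 correlated at r = 0.74 with a covariance of 0.342, days 1 and 3 at 0.44 with 0.148, and days 1 and 7 at 0.39 with 0.146, against r = 0.50 and a covariance of 0.027 in the simulated sets. The 2 normoxia arrays could not be split into separate controls, so part of the excess over independent lists may come from sharing them. Days 3 and 7 also lay together in 1 slide row, and normoxia and day 1 in the other. The closer agreement of days 3 and 7 therefore cannot be told apart from an effect of row.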

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

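The list tests between consecutive groups, the choice to look at genes called in opposite directions, and every test of an explanation except that of gene brightness were chosen after the results were seen. The differences in this part were tested within the limma model or with camera, and genes are those named in the text that were called in opposite directions against normoxia in consecutive groups.

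Between day 1 and day 3, the median log2 change was 2.81 for choroid plexus markers (adjusted p = 1.91e-12), -3.09 for striatum markers (adjusted p = 4.65e-11), 0.75 for ependyma and cilia markers, 0.68 for red blood cell genes, 0.28 for ribosomal proteins and 0.26 for oxidative phosphorylation. It was -0.49 for neocortex, -0.33 for cytosolic heat shock, -0.32 for thalamus, -0.31 for circadian clock genes, -0.25 for angiogenesis, -0.15 for microglia and -0.12 for HIF targets. Between day 3 and day 7 it was -2.83 for choroid plexus markers (adjusted p = 4.66e-16), 0.38 for cholesterol synthesis, 0.30 for interferon response, 0.30 for red blood cell genes, 0.25 for microglia, 0.19 for oxidative phosphorylation, 0.19 for ribosomal proteins and 0.16 for thalamus. It was -0.31 for leptomeninges, -0.26 for ependyma and -0.25 for angiogenesis. None of these lists passed with an estimated correlation, where the adjusted p was 0.0515 for choroid plexus and for striatum from day 1 to day 3, 0.0639 for choroid plexus from day 3 to day 7, and higher for the others.

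Genes that were higher than normoxia on day 1 and lower on day 3 had these log2 changes from day 1 to day 3: Drd2 -4.64, Rgs9 -3.49, Penk -3.42, Tac1 -3.31, Coch -2.86, Dusp1 -2.78, Seli -2.74, Lamp5 -1.87, Csf1r -1.47, Cnp -1.46, Aldoa -1.35, Cldn11 -1.31, Tmem119 -1.16, Egr2 -1.12, Nr1d1 -1.11, Ramp3 -0.89, Arc -0.87, Fos -0.85, Mlc1 -0.81, Pdk1 -0.63 and Calb1 -0.49. Pdk1 was not called against normoxia on day 3 under median centring (-0.13). Vegfb and Lhx8, not above background on day 3, were at least 37.5-fold and at least 46.7-fold lower there. Genes lower on day 1 and higher on day 3 were Ttr at 6.96 (not called against normoxia on day 3 with quantile normalization, 0.064), Otx2 at 2.20, Fam183b at 1.47, Rsph1 at 1.23, Foxj1 at 1.08 and Bdnf at 1.02, and Tmem27 and Glycam1, not above background on day 1, rose at least 158-fold and at least 91.5-fold. From day 3 to day 7, genes that went from below to above normoxia were Seli at 3.06, Mx1 at 1.102, Sqle at 0.71 and Ndufa10 at 0.57, and Adam32, not above background on day 3, rose at least 3.71-fold. Genes that went from above to below it were Tmem27 at -5.78 (above background on 1 of 2 day 7 arrays), Ttr at -4.07, Otx2 at -2.49, Rsph1 at -0.69 and Bdnf at -0.49 (under median centring Bdnf was at 0.077 against normoxia on day 7 and not called), and Glycam1, not above background on day 7, was at least 55.9-fold lower.

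Choroid plexus markers were low on days 1 and 7 but not on day 3, and striatal markers were high on day 1. Days 1 and 7 lay in slide columns 3 and 4, and normoxia and day 3 in columns 1 and 2. An effect of column was not tested. Among quantile normalization, median centring, normexp background correction and the authors' values, the day 1 choroid plexus median nearest to 0 was -1.77. These alternatives left the day 1 median of all genes between -0.061 and -0.018, so a large shift of the list was unlikely. The result therefore shows only that the choice among them does not remove the falls. Different amounts of choroid plexus in the dissected tissue cannot be told apart from a response of the choroid plexus: 19 of 20 members fell on both days, which either would give, and the day 3 median of -0.078 is open to both because each group may hold its own amount. Striatal tissue in the day 1 samples cannot be told apart from a rise of these genes in the hippocampus, since either would raise the markers, and 15 of 15 rose. Ttr lay 6.90 log2 above the 75th percentile in normoxia, all 20 choroid genes and 14 of the 15 striatal genes were above background there, and 1 and 2 of them are on another list.

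Ribosomal protein and oxidative phosphorylation genes were high on day 7. Probe GC is argued against as the whole cause, since with its trend removed the medians were 0.51 and 0.22 with both lists still called; with normexp background correction the oxidative phosphorylation list lost its call (median 0.25, adjusted p = 0.718), and the cause was not tested. For ribosomal genes the median lay at percentile 99.71 of level-matched lists, beyond the 99th percentile set before this was seen. Those lists had a median of 0.41 against the observed 0.50. They were drawn as independent genes, and draws beyond the brightest gene were set to that gene. Such lists vary less than lists of genes that move together, so the test cannot decide and brightness stays open as a cause. With quantile normalization the medians were 0.066 and -0.094. That method gives all arrays 1 distribution of signals, so it pulls bright genes as a group toward 0 whether their rise is technical or real. The scaling of bright genes between arrays may account for both patterns, but this result cannot decide it. A response to the exposure stays open and was not tested.

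Red blood cell genes were high on every day. More whole blood of unchanged composition left in the tissue would raise neutrophil genes too. The 6 tested were chosen after the data were seen and went apart, from -1.305 for Ngp to 0.49 for Camp on day 7. On days 3 and 7 the neutrophil medians were -0.13 and -0.066, with median absolute deviations of 0.16 and 0.54. The red blood cell medians were 1.65 and 1.98. Platelet genes rose in part, with medians smaller than those of the red blood cell genes (3 of 7 rose on day 3, median 0.365, and 4 of 7 on day 7, median 0.21, with none falling). On day 3 the platelet gene Pf4 rose by more than the red blood cell median. Neutrophil and platelet genes thus disagree, and more whole blood stays open on days 3 and 7. On day 1 it stays open, since the neutrophil median was 0.079 with a median absolute deviation of 0.93, against 0.97, and S100a8 (1.35) and S100a9 (1.72) rose, as did 3 of 7 platelet genes; 4 of the 6 neutrophil genes are on another list. More red cells, or younger ones, in the blood of exposed rats may also raise these genes and was not tested.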

How the results depend on the processing

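Removal of the probe GC trend, the fit without the day 1 arrays and the counts without neighbouring-tissue genes were chosen after the data were seen; the other alternatives were planned. In leave-one-out fits the lone array of a group is assumed to vary like the others. Of the comparisons of a count with an alternative, 130 stayed within 1.5 times and 16 did not. With a fold of 2 added to the adjusted p, 761, 1509 and 2420 genes passed against normoxia on days 1, 3 and 7, 1380 from day 1 to day 3 and 650 from day 3 to day 7, and with an unadjusted p it was 889, 1629 and 2519 against normoxia; a stricter threshold by construction lowers a count. Day 7 against day 3 gave 5358 with only the 2 groups, and 7654 genes were shared by days 3 and 7 without the day 1 arrays, where 1 comparison fewer is asked for. Leaving out 1 array gave 4350 to 7669 genes for day 1, 8253 to 10919 for day 3, 11083 to 12992 for day 7, 8060 to 11051 for day 3 against day 1, 6779 to 8323 for day 7 against day 3, 13855 to 15047 for any difference, and 1668 to 2720 for genes called in all 3 comparisons with normoxia. With the replicate number as a block the counts were 6932, 10290 and 12702 against normoxia, 10387 and 8428 between groups, 14918 for any difference and 2552 in all 3. With the GC trend removed, 7425, 10647 and 12810 genes were called on days 1, 3 and 7, and without neighbouring-tissue genes 7480, 10654 and 12970. The latter counts only drop the list members, so they cannot test for neighbouring tissue among the other genes. Direction reversed for Adm from day 1 to day 3 (0.0041, median centring), Bdnf on day 7 (0.077, median centring), Hif3a on day 7 (0.43, normexp, not called in the main scaling), and oxidative phosphorylation with quantile normalization on day 3 (-0.13) and day 7 (-0.094); the cause was not tested. Under median centring the day 7 medians of neocortex (0.065) and thalamus (0.017) markers also turned positive and both lists lost their call, while their direction relative to other genes stayed down. Of the other values for genes, 5094 were unchanged in direction and call, 71 lost the call, 5 gained it and 34 moved; for lists these were 2034, 80, 47 and 57. Signal over background limits the dimmest genes, for which folds are lower bounds.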

Other observations

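Genes and lists in this part were chosen after the data were seen, except the 37 fixed lists. The midbrain dopamine neuron and hypothalamic neuropeptide lists hold genes that had been seen to fall (Slc6a3, Foxa2 and Pmch), so only the counts of their members are given. All 12 and all 10 members were above background in normoxia. Different amounts of such tissue in the samples cannot be told apart from a response to the exposure. Of 12 midbrain dopamine neuron genes, 8 fell and 1 rose on day 1, 8 fell and none rose on day 3, and 7 fell and 1 rose on day 7. Slc18a2, the vesicular monoamine transporter gene, was at -3.14 ± 0.21, -2.64 ± 0.21 and -2.10 ± 0.21 on days 1, 3 and 7, and Th, of dopamine synthesis, at -0.87 ± 0.23, -1.98 ± 0.23 and -2.45 ± 0.23. Th lost its day 1 call in several fits, such as those without normoxia replicate 2 (-0.62), day 1 replicate 1 (-1.08), day 1 replicate 2 (-0.66) or either day 3 array (-0.87). Of 10 hypothalamic neuropeptide genes, 6 fell and 1 rose on day 1, with Cartpt at -1.28 ± 0.04, 3 fell and 2 rose on day 3, and 3 fell and 3 rose on day 7. Of 7 platelet genes, 3 rose on day 1 (adjusted p = 0.0267, and adjusted p = 0.212 with an estimated correlation), with Pf4 at 0.77 ± 0.06, and on days 3 and 7, with Pf4 at 2.40 ± 0.06 and 1.39 ± 0.06, 3 and 4 rose, none fell and the list did not pass (adjusted p = 0.168 and 0.279). Neutrophil genes did not pass on any day (adjusted p = 0.334, 0.319 and 0.892), with S100a8 at 1.35 ± 0.06 and S100a9 at 1.72 ± 0.11 on day 1.

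Several fixed lists passed on none of the 3 days, with members going both ways. Pericyte and smooth muscle markers went both ways: Tagln was at -2.30 ± 0.05 and Kcnj8 at 1.56 ± 0.04 on day 7, with 5 of 15 rising and 7 falling (adjusted p = 0.498). On day 1 the antioxidant gene Hmox1 rose by 1.06 ± 0.04 among 8 rising and 9 falling of 29 (adjusted p = 0.710), and the chaperone gene Hspa1b by 0.72 ± 0.04 among 7 rising and 5 falling of 21 heat shock genes (adjusted p = 0.123). Il1b rose by 1.48 ± 0.04 among 8 rising and 12 falling of 33 inflammatory mediators (adjusted p = 0.883), and Pdia4 by 1.20 ± 0.04 among 11 rising and 10 falling of 34 ER stress genes (adjusted p = 0.290). The interneuron list gene Tac1, which striatum also expresses, rose by 2.42 ± 0.05 among 7 rising and 6 falling of 19 (adjusted p = 0.531). On day 7 the clock gene Nr1d1 was at -1.01 ± 0.08, with 3 of 14 clock genes rising and 6 falling (adjusted p = 0.410), and the CA list gene Coch at -2.51 ± 0.03, with 7 of 16 rising and 4 falling (adjusted p = 0.649). Dentate granule cell markers rose in 3 and fell in 3 of 14 cases on day 7 (adjusted p = 0.498), astrocyte markers rose in 10 and fell in 8 of 22 (adjusted p = 0.743; median -0.13, at percentile 0.19 of level-matched lists with 0.25), and perivascular macrophage and leukocyte markers rose in 3 and fell in 3 of 13 (adjusted p = 0.649). Other lists that did not pass lay below the 1st percentile of level-matched lists: thalamus on day 1 (percentile 0), oxidative phosphorylation (0.01), striatum (0.11), pericyte and smooth muscle (0.14), heat shock (0.43), myelin (0.67), oligodendrocyte precursor (0.88) and interneuron (0.89) lists on day 3, and neurogenesis (0.58), interneuron (0.69) and heat shock (0.77) lists on day 7. The cell cycle list on day 3 lay at percentile 100. Since level-matched lists were drawn as independent genes, they vary less than lists of genes that move together. These percentiles therefore cannot decide whether a list changed.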
